A study of Homo sapiens with 24 samples.

How the data were processed

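RNA was measured by sequencing of poly(A)-selected libraries from 24 cultures or preparations of human prostate cells. Per the labels, PC3 cells were transfected for 24 hours with a scrambled control siRNA (Scr) or with 1 of 2 siRNAs (si1, si2) against ZBTB33, ZBTB38 or ZBTB4. PrEC, normal prostate epithelial cells, were grown in another medium and used at a lower range of passages, and no transfection is described for them. Each of the 8 groups held 3 libraries.

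The deposited table holds raw read counts per Ensembl gene, whole numbers that the authors made with STAR 2.5.2b for alignment to GRCh38 and featureCounts 1.5.1 for counting. FastQC, MultiQC and DESeq2 1.16.0 are also listed, without their roles. The annotation release, the strand setting and the handling of reads with several matches are not stated. The table holds 58051 genes, of which 57447 were found by identifier in GENCODE 29 (GRCh38), the source of names and positions. Where the exons of a named gene overlap those of another gene by 10% or more, this is stated beside it, since the strand setting is unknown. All 24 columns were matched to a sample by its label.

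Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group (min.count 10, min.total.count 15), libraries were scaled with TMM, and groups were compared by the quasi-likelihood F test, two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The 21 PC3 libraries were fitted together with 1 coefficient per group, which left 16965 genes and 99.9% of counts. The common biological coefficient of variation was 6.1%. PrEC and Scr were fitted apart from the other groups, in 6 libraries with 16512 genes, 99.87% of counts and a coefficient of 6.8%. Standard errors of log2 changes were taken from the change and its F statistic. Expression in CPM was computed with TMM-scaled library sizes and is given as mean and SD over the 3 libraries of a group. PrEC was put on the PC3 scale through the Scr libraries.

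For each target, si1 and si2 were each compared with Scr, with each other, and as a mean with Scr and with the 4 siRNAs of the other targets. A gene was counted as called alike when it passed with both siRNAs (or with all 6) in 1 direction. Because these comparisons share the Scr libraries, they were also run on 20 simulated data sets in which no group differed. Correlations of log2 changes were taken across genes, which are not independent replicates, so no p-value is given for them.

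Gene lists for 27 pathways and cell states were written before the data were examined, as were all comparisons, the rule for named genes and the alternatives, except where a choice is described as made later. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and adjusted over the 27 lists. Camera with an estimated correlation and fry were alternatives. A list's members are counted as called over all genes tested and adjusted over the list alone, a count in which the Benjamini-Hochberg step runs over the members only. Markers of 5 cell types were also fixed and are given as levels.

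Named genes were chosen by a fixed rule. It took the 3 targets. For each target it took the 10 largest rises and 10 largest falls of the mean of both siRNAs among genes called alike, with a mean of at least 2 CPM over the PC3 libraries. The same numbers were taken for genes called alike with all 6 siRNAs. For PrEC it took the 12 largest rises and falls at a mean of at least 10 CPM, for comparisons between siRNAs or between targets the 3 largest in each direction, and from each list the up to 4 members with the smallest adjusted p. Genes outside the rule are marked where they appear.

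Library totals ran from 16915027 to 22685242 counts. A floor of 3 counts was used for groups at 0, which is 0.132 to 0.177 CPM in a single library. Folds against a group at 0 counts were computed against 3 counts over the group and are lower bounds. For 1 to 3 counts over the group, the ratio is given with its exact 95% binomial (Clopper-Pearson) interval. Reads carry no molecular identifiers, so floors and intervals cover counting error only.

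The alternatives were DESeq2 size factors, library totals without scaling factors, no low-count filter, the DESeq2 1.42.0 Wald test, other sets of libraries in the fit, a minimum change of 1.5-fold, and leaving out each library in turn. A term for runs of 10 sample numbers (1 to 10, 11 to 20, 21 to 30), either siRNA alone for the lists, and a test of the mean of both siRNAs in place of each were further alternatives. After the data were seen, genes whose 3' UTR holds a 7-base word linked to an siRNA were also left out. Those words were searched among 16384 words in the 3' UTRs of 11637 genes, by the shift of the log2 changes of genes that hold a word.

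The steps were tested on simulated data. With planted changes of 1.5-fold, the test recovered 98.5% of genes for ZBTB33 si1, 97.7% for PrEC and 96.6% for the mean of the ZBTB33 siRNAs, and called at most 0.074% of unchanged genes. A planted list came first in each of these comparisons, with 3 other lists called in the first. Changes were planted in a small part of the genes, all well above the count filter, and every gene had the same simulated variation. The recovery therefore does not cover genes near the filter, and the rates do not cover genes with a wide spread or data in which most genes change. A planted word was the lowest in 20 of 20 draws, and without one the lowest z was -4.3. Genes on the Y chromosome and XIST were left out of the tables that give values per gene.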

Results

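The series compares ZBTB33 (also called Kaiso), ZBTB38 and ZBTB4, zinc finger proteins that bind methylated DNA, in prostate cancer cells. PC3, an androgen-independent line from a bone metastasis of prostate adenocarcinoma, received a scrambled siRNA (Scr) or 1 of 2 siRNAs against each gene. PrEC, normal prostate epithelial cells in culture, were the only cells that were not PC3. Read counts per gene were analysed for 24 libraries, 3 in each of 8 groups. Library totals ran from 16915027 counts (ZBTB4 si1 replicate 3) to 22685242 counts (ZBTB38 si1 replicate 1). The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

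The sample numbers in the labels fall into 3 runs of 10. Scr and both ZBTB33 groups stand in the first run, both ZBTB4 groups in the second and both ZBTB38 groups in the third, with 1 PrEC library in each. The labels do not call these runs batches. No Scr library used here lies in the second or the third run, so for ZBTB4 and ZBTB38 the target and the run cannot be told apart, and only the 3 PrEC libraries allow a run term in a fit. With 1 PrEC library in each run, such a term also widens standard errors, so a call lost with it need not mean a smaller change. Of the variance among PC3 libraries, 58.7% lay between runs, 23.1% between siRNAs within a run and 18.2% between replicates. The first principal component held 38.2% of the variance and the second 21.4%.

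**Figure D1:**
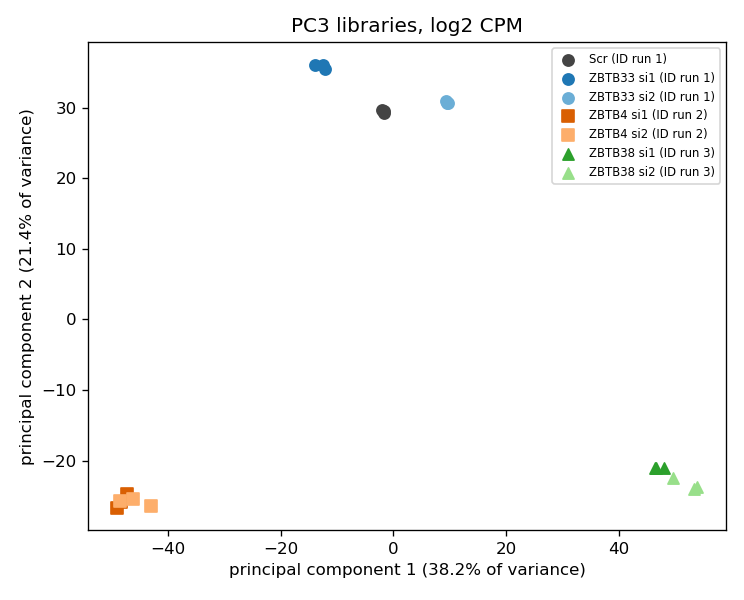
Principal components of log2 CPM of the 21 PC3 libraries, with the percent of variance on each axis and 1 point per library, coloured by group. The first component holds 38.2% of the variance, of which 97.1% lies between the runs of sample numbers, and the second holds 21.4%.

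Each siRNA lowered its own target in every library. ZBTB33 (ENSG00000177485, GRCh38 chromosome X, 120250752 to 120258398, plus strand) fell from 52.1 ± 1.7 CPM in Scr to 5.17 ± 0.78 with si1 and 5.47 ± 0.60 with si2 (mean ± SD, n = 3 per group), which is 9.93% and 10.5% of Scr. ZBTB38 (ENSG00000177311, chromosome 3, 141324213 to 141449792, plus strand) fell from 89.9 ± 3.1 CPM to 6.58 ± 0.12 and 8.41 ± 0.18, or 7.31% and 9.35%. ZBTB4 (ENSG00000174282, chromosome 17, 7459366 to 7484263, minus strand) fell from 87.2 ± 4.6 CPM to 12.1 ± 0.55 and 12.5 ± 1.5, or 13.9% and 14.4%. The log2 changes were -3.33 ± 0.18 (SE) and -3.25 ± 0.18 for ZBTB33, -3.77 ± 0.07 and -3.42 ± 0.06 for ZBTB38, and -2.85 ± 0.07 and -2.80 ± 0.07 for ZBTB4. The highest adjusted p among these 6 tests was 9.9e-13.

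The genes also moved with siRNAs against each other. ZBTB38 fell to 56.2% of Scr with ZBTB33 si2 (log2 change -0.83 ± 0.05, adjusted p = 1.3e-11) and to 91.3% with ZBTB33 si1 (-0.13 ± 0.05, adjusted p = 0.0371). That last value is the highest of its 6 siRNAs, and its call with all 6 ended with the DESeq2 test (highest adjusted p = 0.0578) and without a low-count filter (0.193). The call also ended without Scr replicate 2 (0.0609) or 3 (0.140), and without ZBTB33 si1 replicate 1 (0.141) or 2 (0.0823). With the ZBTB4 siRNAs, ZBTB38 fell to 60.2% (si1, adjusted p = 3.2e-11) and 82.9% (si2, adjusted p = 9.9e-05). With the run as a term, ZBTB38 was called with 4 of the 6 siRNAs (highest adjusted p = 0.585), at a mean log2 change of -1.47 against -1.53 without it. ZBTB4 rose to 147% and 138% of Scr with the ZBTB38 siRNAs (adjusted p = 2.8e-08 and 4.2e-07) and was at 101% and 103% with the ZBTB33 siRNAs (adjusted p = 0.901 and 0.674). ZBTB33 fell to 68.8% with ZBTB38 si1 (adjusted p = 0.00254) and stood at 80.1% with ZBTB38 si2 (adjusted p = 0.0595). With the ZBTB4 siRNAs it stood at 80.8% and 93.5% (adjusted p = 0.0717 and 0.600).

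**Figure D2:**
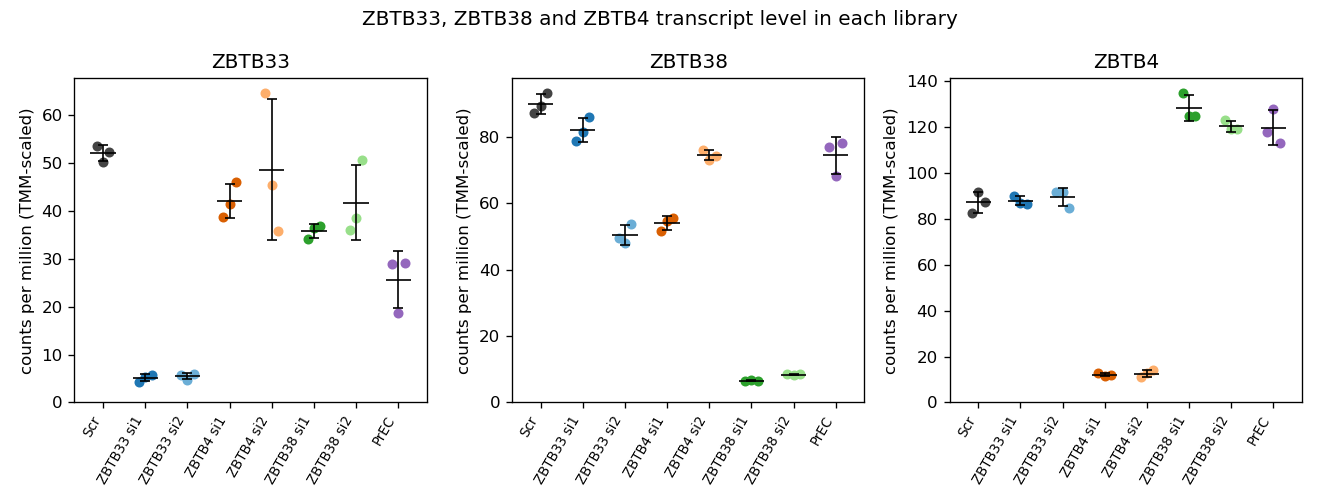
Expression of ZBTB33, ZBTB38 and ZBTB4 in CPM for each of the 8 groups, with bars for the mean of 3 libraries, points for single libraries and error bars for 1 SD. Each gene is lowest in the 2 groups treated against it, at 7.31% to 14.4% of Scr.

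The first question was which genes change when ZBTB33 is lowered. With both ZBTB33 siRNAs, genes of the amino acid and endoplasmic reticulum stress response rose, and genes of DNA replication fell. The stress list also rose with the siRNAs against ZBTB38 and ZBTB4, compared with the same Scr libraries, so its rise is not particular to ZBTB33. In the mean of both siRNAs, 22 of 28 measured genes of the stress list were higher and 1 was lower (median log2 change 0.40, camera adjusted p = 2.5e-17), of which 13 rose with each siRNA. HSPA5, the main chaperone of the endoplasmic reticulum, changed by 0.54 ± 0.03 (SE), HERPUD1, which acts in the removal of misfolded proteins, by 0.85 ± 0.04 and STC2, a secreted glycoprotein, by 0.73 ± 0.03. Of 36 genes of DNA replication and S phase, 23 were lower and 1 higher (median -0.27, adjusted p = 2.1e-08), 18 of them lower with each siRNA. EXO1, a DNA exonuclease, changed by -0.76 ± 0.06, and MCM4, a part of the replicative helicase, by -0.50 ± 0.03. Counts adjusted over the list alone equalled those over all genes unless a second count follows.

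Immediate early genes were higher in 13 of 22 cases and lower in 1 (median 0.34, adjusted p = 1.9e-06), among them SPRY4 (0.78 ± 0.04) and DUSP5 (0.64 ± 0.03), feedback inhibitors of growth factor signalling. Of 25 genes of cholesterol synthesis and uptake, 13 were higher, or 14 adjusted over the list alone, and 4 lower (median 0.21, adjusted p = 5.6e-04), with INSIG1 at 0.70 ± 0.07. YAP and TEAD target genes were higher in 12 of 23 and lower in 4 (median 0.22, adjusted p = 0.00346), with PTPN14 at 0.63 ± 0.04 and ANKRD1 at -0.90 ± 0.07. Hypoxia and glycolysis genes were lower in 16 of 26, or 18 adjusted over the list alone, and higher in 3 (median -0.23, adjusted p = 6.0e-05), but 2 were lower with each siRNA and the median with si2 alone was 0.09. With si2 alone, the immediate early, cholesterol and YAP lists were not called either (adjusted p = 0.130, 0.870 and 0.164). These 6 lists were also called with an estimated correlation.

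A further 5 lists passed at the preset correlation only. Oxidative phosphorylation was lower in 19 of 28 (median -0.17, adjusted p = 0.00124, and adjusted p = 0.183 with an estimated correlation). Nucleolar genes were lower in 10 of 26 (median -0.08, adjusted p = 0.0219, against adjusted p = 0.290 estimated), and genes of G2 and mitosis in 11 of 30 (median -0.11, adjusted p = 0.0228, against adjusted p = 0.283 estimated), with PRC1 (64.9% overlap with ENSG00000284946) at 0.02 with si1 (adjusted p = 0.730) and -1.28 with si2. Integrins, laminins and matrix proteases were higher in 11 of 27, or 12 adjusted over the list alone, and lower in 4 (median 0.17, adjusted p = 0.0228, against adjusted p = 0.181 estimated). ITGB6, an epithelial integrin subunit, went the other way at -1.62 ± 0.10, while MMP1, a collagenase, stood at 1.23 ± 0.11. Epithelial junction genes were higher in 13 of 29, or 15 adjusted over the list alone, and lower in 7 (median 0.12, adjusted p = 0.0493, against adjusted p = 0.391 estimated), with JUP at 0.60 ± 0.06, and GRHL2 at -0.75 with si1 and 0.04 with si2 (adjusted p = 0.582). That call also ended without Scr replicate 3 (adjusted p = 0.0931), ZBTB33 si1 replicate 1 (0.0809) or si2 replicate 3 (0.0598), and with library totals (0.0634). With si1 alone, none of these 5 lists was called: adjusted p = 0.131 for oxidative phosphorylation, 0.361 for nucleolar genes, 0.705 for G2 and mitosis (median -0.04), 0.137 for integrins and 0.131 for epithelial junctions. With si2 alone, the epithelial list gave 0.182, and without genes that hold siRNA-linked words the G2 list gave 0.115. The other 16 lists gave adjusted p from 0.0519 to 0.960.

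Besides ZBTB33, the genes that fell most with both siRNAs were HPRT1, an enzyme of purine salvage (4.40-fold lower, log2 change -2.14 ± 0.11), MTPN (3.97-fold), LYRM1 (3.82-fold) and GKN2 (3.68-fold, but -3.39 with si1 and -0.37 with si2). NOX5, an NADPH oxidase, was 3.38-fold lower, STEAP4, a metalloreductase, 3.22-fold, BPNT2 3.12-fold and PLAAT3 2.90-fold (-2.87 with si1, -0.20 with si2). Exons of NOX5 overlap AC027088.1 by 10.3%, and those of ITGB6 overlap ENSG00000285155 by 20.6%. The largest rises were those of MCPH1-AS1 (4.24-fold, 13.3% overlap with MCPH1), PTPMT1 (3.48-fold, 77.6% overlap with KBTBD4), SLC36A1, an amino acid transporter (3.24-fold), GPX2 (3.20-fold) and CALU, a calcium-binding protein of the endoplasmic reticulum (3.17-fold). GSDMC, TC2N, ADM2 and BOD1 rose 2.76-fold to 3.18-fold. STEAP4, ITGB6, PTPMT1, SLC36A1, TC2N and ADM2 also moved in 1 direction with all 6 siRNAs, so their changes are not particular to ZBTB33. KRT17, a basal keratin, was also among the 10, but its rise with si2 was 0.31 (adjusted p = 0.453) without replicate 2, where it stood at 38.7 CPM against 10.7 CPM in the other 2. That library held PrEC transcripts at 0.246% of their PrEC level, which for KRT17 comes to 43.6 CPM. The highest adjusted p among the 20 was 2.7e-04 (KRT17), and in all 20 the 6 knockdown libraries lay on 1 side of the Scr mean. The choice of large changes in 1 direction makes such a position likely, so it adds no separate support.

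With ZBTB33 si1, 7963 of 16965 genes were called (3958 higher, 4005 lower), and with si2 5487 (3060 higher, 2427 lower), or 2958 and 1250 at 1.5-fold or more. The siRNAs had 2117 genes in common in direction (1198 higher, 919 lower), against 714 and 573 for independent lists of these sizes, and 1307 genes in opposite directions, against 1289 for independent lists. The log2 changes of si1 and si2 had r = 0.221 across genes and a covariance of 0.0516. Agreement with siRNAs of other targets was in part higher. ZBTB33 si1 had r of 0.335 and 0.333 with the ZBTB4 siRNAs and 0.213 and 0.232 with those of ZBTB38. ZBTB33 si2 had r of 0.364 and 0.362 with the ZBTB38 siRNAs and 0.133 and 0.141 with those of ZBTB4. By this measure over all genes, the agreement of the ZBTB33 siRNAs is therefore not particular to ZBTB33. Of genes alike with both, 705 also rose and 493 also fell with both ZBTB38 siRNAs (290 and 197 for independent lists), and 208 went the other way. With both ZBTB4 siRNAs, 689 also rose and 364 also fell (232 and 172 for independent lists), and 178 went the other way. In 20 simulated data sets with no change, the shared Scr libraries alone gave 0 genes alike, r of 0.470 to 0.514 and covariances of 0.0177 to 0.0203. The 3 Scr libraries cannot be divided into separate sets of at least 2, so part of the excess may come from the shared controls. Requiring a change of 1.5-fold with each siRNA left 290 genes.

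For ZBTB38, the interferon response was the main change. All 34 measured interferon genes were higher with both siRNAs (median log2 change 1.98, camera adjusted p = 1.8e-143, and adjusted p = 2.1e-12 with an estimated correlation). BST2, an antiviral membrane protein, rose 17.7-fold (log2 change 4.15 ± 0.07, SE), RSAD2, an antiviral enzyme, 12.8-fold, OASL by 3.43 ± 0.05 and IFI6 by 3.21 ± 0.05. GBP5 (18.7-fold), APOL1 (16.9-fold) and the chemokine CXCL11 (16.8-fold) were also among the 10 largest rises. Hypoxia and glycolysis genes rose in 23 of 26 and fell in 1 (median 0.71, adjusted p = 3.7e-20), with ANGPTL4 at 3.11 ± 0.09, ENO2 at 1.38 ± 0.04 and PGK1 at 0.84 ± 0.03. Mesenchymal genes rose in 15 of 21 and fell in 3 (median 0.72, adjusted p = 8.9e-09), with VIM, an intermediate filament protein, at 1.11 ± 0.03 (24.4% overlap with VIM-AS1), SPARC at 1.69 ± 0.06 and COL6A1 at 1.33 ± 0.06.

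Epithelial junction genes fell in 23 of 29 and rose in 3, or 4 adjusted over the list alone (median -0.50, adjusted p = 1.4e-11). ESRP1, a splicing regulator of epithelial cells, changed by -1.52 ± 0.05, GRHL2 by -1.42 ± 0.04, EPCAM by -0.94 ± 0.04 and CDH1, E-cadherin, by -0.79 ± 0.03. Cholesterol genes fell in 21 of 25, or 22 adjusted over the list alone, and rose in 1 (median -0.62, adjusted p = 6.6e-11), among them INSIG1 (-1.41 ± 0.06), ACAT2 (-1.10 ± 0.04, 69.7% overlap with SOD2-OT1) and SQLE (-1.05 ± 0.04). Genes of G2 and mitosis fell in 26 of 30 and rose in 2 (median -0.52, adjusted p = 8.6e-11), with CCNB1, cyclin B1, at -0.71 ± 0.04 and BIRC5, survivin, at -0.64 ± 0.03. The amino acid and endoplasmic reticulum stress list rose in 19 of 28 and fell in 4 (median 0.35, adjusted p = 2.4e-08), with DDIT3, also called CHOP, at 1.80 ± 0.07 (39.6% overlap with MARS1). The NF-kB and inflammatory list rose in 17 of 26 and fell in 5 (median 0.50, adjusted p = 0.00114), with ICAM1 at 1.59 ± 0.06 (23.6% overlap with ICAM4-AS1) and CSF1 at 2.03 ± 0.10. These 8 lists were also called with an estimated correlation.

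Another 5 lists passed at the preset correlation only. Lysosome and autophagy genes rose in 17 of 24 and fell in 4 (median 0.44, adjusted p = 1.9e-05, against adjusted p = 0.0717 estimated), with SQSTM1, an autophagy receptor, at 1.41 ± 0.04 (22.0% overlap with MRNIP). Immediate early genes rose in 14 of 22 and fell in 3 (median 0.52, adjusted p = 2.0e-04, against adjusted p = 0.0757 estimated), with KLF4 at 1.41 ± 0.05. NRF2 and oxidative stress genes rose in 13 of 23 and fell in 6 (median 0.21, adjusted p = 0.0117, against adjusted p = 0.0717 estimated), with HMOX1, heme oxygenase 1, at 2.93 ± 0.09 and NQO1 at -0.64 ± 0.03 (17.7% overlap with ENSG00000261602). Oxidative phosphorylation fell in 15 of 28 and rose in 2 (median -0.17, adjusted p = 0.00272, against adjusted p = 0.179 estimated). Luminal prostate and androgen response genes fell in 8 of 15 and rose in 3 (median -0.23, adjusted p = 0.0233, against adjusted p = 0.0542 estimated), with ALDH1A3 at -1.27 ± 0.03 (28.6% overlap with ALDH1A3-AS1). That call also ended without Scr replicate 2 (adjusted p = 0.0528), without ZBTB38 si2 replicate 3 (0.0574), with the run as a term (0.0709), without a low-count filter (0.153) and with only the compared groups in the fit (0.0614). With si2 alone, the NRF2 list gave adjusted p = 0.0592. The other 14 lists gave adjusted p from 0.0984 to 0.921. Of these, RNA interference genes were called without a low-count filter (0.0119), with the run term (0.0463) and with si2 alone (0.0497), integrins with si1 alone (0.0497) and without genes that hold siRNA-linked words (0.0172), and TGF-beta targets without those genes (0.0215). Basal genes were called without a low-count filter (0.0324), and DNA replication with si2 alone (0.0461).

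Apart from ZBTB38 itself, the largest falls were DMBT1, a secreted mucosal protein (10.9-fold lower), RFX6, a transcription factor (9.67-fold), CALB2, calretinin (7.26-fold), LMX1B (6.83-fold), ADD2 (6.83-fold) and EFS (5.64-fold). SERTAD4, METTL7A and KLK5 (12.2% overlap with ENSG00000269495) fell 5.24-fold, 5.06-fold and 4.48-fold. Among other rises, LINC00520 rose 16.1-fold, CRABP1, which binds retinoic acid, 15.6-fold (47.2% overlap with ENSG00000279694), TFF3 14.4-fold, PDE10A 14.4-fold and ANXA10 13.3-fold. The highest adjusted p among the 20 was 6.9e-10 (LMX1B), and in all 20 the 6 knockdown libraries lay on 1 side of the Scr mean, which the choice of these genes makes likely. The run term rests on PrEC, which had 1 count of RFX6, 19 of PDE10A and 0 to 4 of CRABP1, LMX1B and ADD2. With it, the log2 change of RFX6 turned to 0.40 ± 0.88 (SE), and that of PDE10A went from 3.85 ± 0.18 to 2.04 ± 1.18 (adjusted p = 0.254). For CRABP1, LMX1B and ADD2, which have no count in at least 2 of the 3 PrEC libraries, the SE was 4046.35 to 6395.96. The term cannot be estimated for them, so their lost calls say nothing about the run. RFX6 also has no count in 2 PrEC libraries, so its turn rests on 1 count.

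ZBTB38 si1 gave 9435 called genes (4985 higher, 4450 lower) and si2 9662 (5106 higher, 4556 lower), or 3695 and 4050 at 1.5-fold or more and 3552 and 3687 with the run term. Of the genes called, 7747 moved alike (4102 higher, 3645 lower), against 1500 and 1195 for independent lists, and 29 moved in opposite directions, against 2678. The siRNAs had r = 0.898 across genes and a covariance of 0.448, against simulated covariances of 0.0180 to 0.0203 and 0 genes alike from the shared Scr libraries. All of these values compare a group of the third run of sample numbers with Scr of the first, so target and run cannot be told apart in them. With the run as a term, carried by the 3 PrEC libraries, 2820 genes were called alike. At 1.5-fold with each siRNA, 2816 were. The term also widens standard errors, among lost calls from 0.05 to 0.17 for CHAF1B (log2 change 0.51 to 0.48). The lower count with the term therefore does not measure a run effect.

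For ZBTB4, the interferon response went the other way. Of 34 interferon genes, 33 fell and 1 rose in the mean of both siRNAs (median log2 change -1.48, camera adjusted p = 9.2e-93, and adjusted p = 1.2e-10 with an estimated correlation), 30 of them lower with each siRNA. BST2 was 37.8-fold lower (log2 change -5.24 ± 0.13, SE), IFI27 20.3-fold, TRIM22 24.6-fold (10.7% overlap with OR56B1) and MX2 17.9-fold, while OAS1 stood at -3.33 ± 0.04 and OAS2 at -3.44 ± 0.04. The amino acid and endoplasmic reticulum stress list rose in 25 of 28 and fell in 1 (median 0.86, adjusted p = 2.3e-32), with SLC3A2, an amino acid transporter subunit, at 2.01 ± 0.04, HSPA5 at 1.66 ± 0.04 and HERPUD1 at 1.62 ± 0.04. TGF-beta and SMAD target genes rose in 16 of 20 and fell in 4 (median 0.68, adjusted p = 1.1e-09), with THBS1 at 1.52 ± 0.03. YAP and TEAD target genes rose in 19 of 23 and fell in 2 (median 0.65, adjusted p = 3.1e-09), with DLC1 at 1.27 ± 0.06 and AXL at 0.87 ± 0.03.

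Lysosome and autophagy genes rose in 19 of 24 and fell in 1 (median 0.38, adjusted p = 1.6e-07), with SQSTM1 at 1.77 ± 0.04 (22.0% overlap with MRNIP). NRF2 and oxidative stress genes rose in 12 of 23 and fell in 2 (median 0.33, adjusted p = 3.5e-05), with HMOX1 at 2.99 ± 0.09 and FTH1, a ferritin chain, at 1.29 ± 0.07 (62.4% overlap with BEST1). Mesenchymal genes rose in 16 of 21 and fell in 2, or 3 adjusted over the list alone (median 0.68, adjusted p = 3.5e-04), with SNAI2 at 1.74 ± 0.06, but SPARC fell 25.3-fold and COL5A2 stood at -1.15 ± 0.03. Growth arrest and p53 target genes rose in 14 of 29, or 15 adjusted over the list alone, and fell in 10 (median 0.21, adjusted p = 0.0241), with CDKN1A, the inhibitor p21, at 1.97 ± 0.07. Luminal prostate genes fell in 8 of 15 and rose in 2 (median -0.66, adjusted p = 1.0e-05), with TMPRSS2 at -1.78 ± 0.05, HOXB13, a prostate transcription factor, at -1.63 ± 0.04 and SPDEF at -1.43 ± 0.06. Genes of G2 and mitosis fell in 21 of 30 and rose in 3 (median -0.36, adjusted p = 3.0e-05), with AURKA at -0.63 ± 0.03. Cholesterol genes fell in 16 of 25 and rose in 1 (median -0.18, adjusted p = 0.00562). With the list above, these 11 were also called with an estimated correlation. The run term ended the calls of the mesenchymal list (median 0.49, adjusted p = 0.0590) and the luminal list (median -0.40, adjusted p = 0.0779) and of TMPRSS2 (log2 change -0.11 ± 0.81, with 18 counts in PrEC). With si1 alone, the growth arrest and cholesterol lists were not called (adjusted p = 0.108 and 0.0986), and without genes that hold siRNA-linked words the mesenchymal and cholesterol lists were not (adjusted p = 0.202 and 0.0665), at medians of 0.64 and -0.13 over fewer genes.

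A further 6 lists passed at the preset correlation only. Immediate early genes rose in 17 of 22 and fell in 4 (median 0.73, adjusted p = 0.00109, against adjusted p = 0.121 estimated), with FOS 13.4-fold higher and DUSP6 at -1.76 ± 0.04 (40.5% overlap with ENSG00000274021). The NF-kB list rose in 15 of 26, or 16 adjusted over the list alone, and fell in 6 (median 0.24, adjusted p = 0.0115, against adjusted p = 0.0757 estimated, and 0.140 with the run term and 0.172 without genes that hold siRNA-linked words), with IL6 at 1.71 ± 0.07 (22.9% overlap with IL6-AS1). Oxidative phosphorylation fell in 22 of 28 (median -0.21, adjusted p = 0.00191, against adjusted p = 0.147 estimated). Epithelial junction genes fell in 18 of 29, or 19 adjusted over the list alone, and rose in 6 (median -0.23, adjusted p = 0.0129, against adjusted p = 0.307 estimated), with CLDN3, a tight junction protein, at -1.21 ± 0.07. The run term cannot be estimated for it, since PrEC has no count of it. Nucleolar genes rose in 17 of 26 and fell in 4 (median 0.20, adjusted p = 0.0209, against adjusted p = 0.295 estimated), with RRS1 at 0.93 ± 0.06 (11.4% overlap with ENSG00000285655). DNA methylation writers, erasers, readers and corepressors rose in 12 of 28 and fell in 7 (median 0.10, adjusted p = 0.0209, against adjusted p = 0.236 estimated, and 0.595 with the run term), with TET3, which oxidises methylated cytosine, 2.23-fold higher and TDG, a DNA glycosylase, at 0.78 ± 0.06. With si1 alone, the NF-kB and oxidative phosphorylation lists gave adjusted p = 0.370 and 0.108, and with si2 alone the epithelial and nucleolar lists 0.249 and 0.568. The other 10 lists gave adjusted p from 0.0843 to 0.848. Of these, integrins (0.0425) and RNA interference genes (0.0441) were called without a low-count filter, and genes described as regulated by these proteins with si2 alone (0.0352) and without genes that hold siRNA-linked words (0.0419).

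The largest rises with both ZBTB4 siRNAs were those of ARC, an immediate early gene of neurons (42.8-fold), FOS, BMP2, a secreted growth factor (10.3-fold), the chemokine CXCL12 (10.1-fold), HMOX1 (7.92-fold) and IL24 (7.46-fold). THSD7A, SLC36A1, MCPH1-AS1 and HKDC1 rose 5.73-fold to 6.99-fold. Besides interferon genes and SPARC, the largest falls were those of MSMP, a secreted protein first described in PC3 cells (33.6-fold lower, from 485 CPM in Scr) and SLC14A1, a urea transporter (22.0-fold). All of the MSMP exons overlap RGP1. FCGR2A, XAF1 (38.3% overlap with PRAL) and KRT20 also fell, from 3.24, 1.22 and 1.44 CPM in Scr to at most 0.152 CPM. The highest adjusted p among the 20 was 4.3e-10 (MCPH1-AS1), and in all 20 the 6 knockdown libraries lay on 1 side of the Scr mean, which the choice of these genes makes likely. PrEC, which carries the run term, had 37 counts of MSMP and 0 to 7 of ARC, CXCL12, THSD7A, MCPH1-AS1 and FCGR2A. With the term, MSMP turned to a log2 change of 1.66 ± 2.57 (SE) and ARC went from 5.42 ± 0.17 to 0.62 ± 2.37. CXCL12 went from 3.34 ± 0.20 to 7.01 ± 3.39 and MCPH1-AS1 from 2.66 ± 0.22 to 2.48 ± 1.55, while the term cannot be estimated for THSD7A and FCGR2A, which have no count in PrEC. None of the 6 was called with the term.

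ZBTB4 si1 gave 8871 called genes (4441 higher, 4430 lower) and si2 8906 (4499 higher, 4407 lower), or 3676 and 3587 at 1.5-fold or more and 3970 and 3830 with the run term. Of the genes called, 6457 moved alike (3284 higher, 3173 lower), against 1178 and 1151 for independent lists, and 216 in opposite directions, against 2328. The siRNAs had r = 0.837 across genes and a covariance of 0.415, against simulated covariances of 0.0180 to 0.0199 and 0 genes alike. ZBTB4 groups stand in the second run of sample numbers and Scr in the first, so target and run cannot be told apart in these values. The run term left 2725 genes called alike, leaving out genes with siRNA-linked words in their 3' UTR 3228, and a minimum of 1.5-fold 2386. The term widens standard errors here too, among lost calls from 0.04 to 0.1 for ATP5F1C (log2 change -0.55 to -0.24). Its lower count therefore does not measure a run effect.

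**Figure D3:**
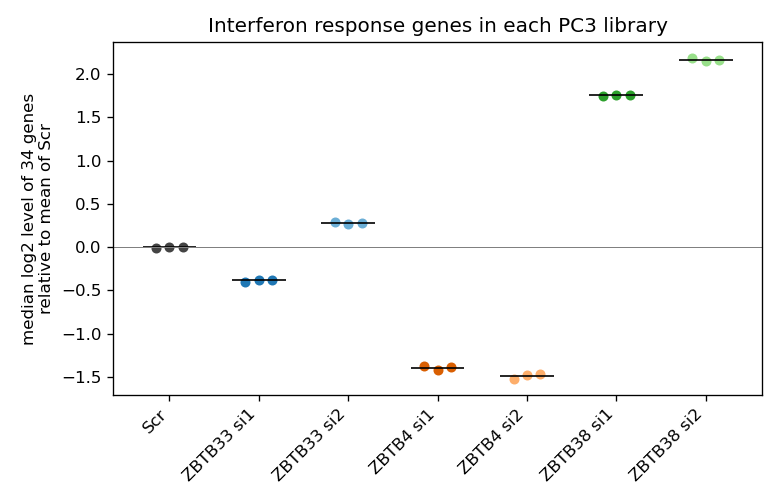
Median log2 difference from the Scr mean of 34 interferon response genes in each of the 21 PC3 libraries, 1 point per library, by group. The ZBTB38 libraries lie between 1.75 and 2.18, the ZBTB4 libraries between -1.52 and -1.38, and the ZBTB33 libraries near -0.38 with si1 and near 0.28 with si2.

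**Figure D4:**
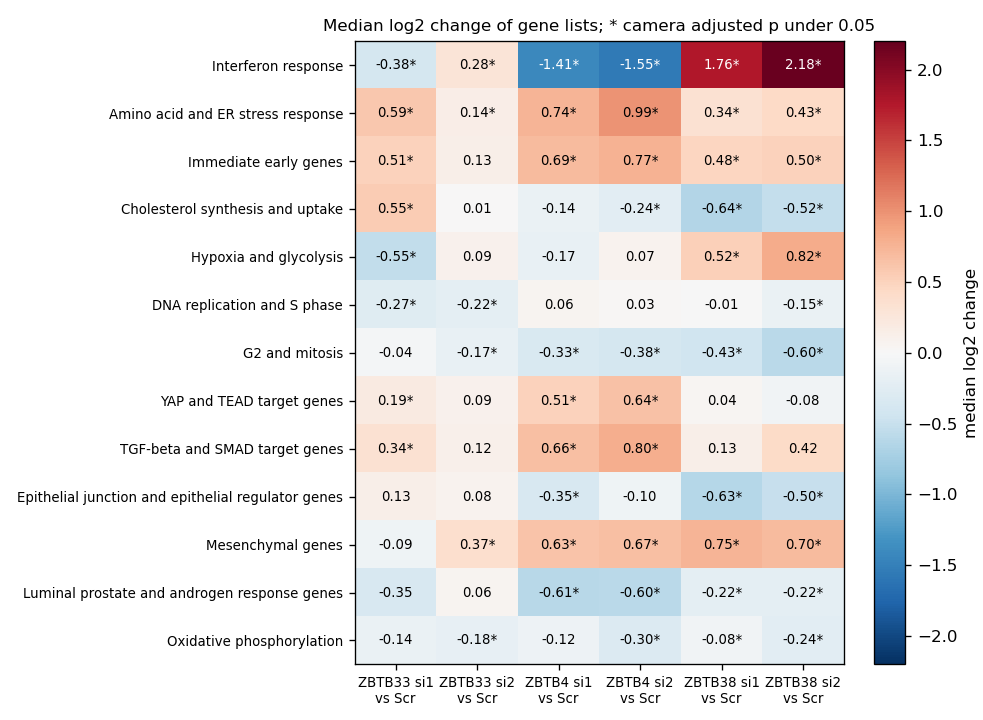
Median log2 change from Scr of a chosen part of the 27 gene lists with each of the 6 siRNAs, as colour and printed value, with an asterisk where the camera adjusted p is below 0.05. Among the lists shown, the interferon list has the highest value with both ZBTB38 siRNAs and the lowest with both ZBTB4 siRNAs.

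The siRNAs of a target were compared with each other without Scr. Between ZBTB33 si1 and si2, 28 of 34 interferon genes were lower with si1 and 1 was higher (median difference -0.69, camera adjusted p = 4.5e-13, and adjusted p = 1.4e-05 with an estimated correlation). Against Scr, the list's median was -0.38 with si1 and 0.28 with si2. Hypoxia genes were lower with si1 in 21 of 26 and higher in 3 (median -0.66, adjusted p = 6.2e-12), stress response genes higher in 20 of 28 and lower in 3 (median 0.37, adjusted p = 4.9e-07), and cholesterol genes higher in 17 of 25 and lower in 3 (median 0.42, adjusted p = 1.6e-04). COL2A1, a cartilage collagen, was 56.9-fold lower with si1, SPARC 16.3-fold and VIPR1 11.3-fold (11.4% overlap with VIPR1-AS1), while C12orf75 was 10.4-fold higher, GAS6-DT 6.99-fold and ADAM9, a membrane protease, 6.14-fold. In all, 8615 genes differed between the ZBTB33 siRNAs (3459 at 1.5-fold or more).

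Between the ZBTB38 siRNAs, 2391 genes differed (1583 with only these groups in the fit, 281 at 1.5-fold or more). Interferon genes were higher with si2 in 31 of 34, or 33 adjusted over the list alone (median difference si1 minus si2 -0.39, adjusted p = 8.9e-48), and hypoxia genes in 20 of 26 (median -0.34, adjusted p = 8.9e-35). ANGPTL4 was 2.49-fold and DEPP1 2.52-fold lower with si1 (23.3% overlap with RASSF4), and SSTR5-AS1 (21.9% overlap with ENSG00000261720), COL4A2 and RAB12 were 2.18-fold, 2.00-fold and 1.84-fold higher. RN7SL2 was 3.87-fold lower with si1 (log2 change -1.95 ± 0.47, adjusted p = 0.00694), but its change was -0.47 (adjusted p = 0.302) without ZBTB38 si2 replicate 3. Without ZBTB38 si1 replicate 1, the count fell to 1527. Between the ZBTB4 siRNAs, 4351 genes differed (2504 with only these groups in the fit, 895 at 1.5-fold or more). NF-kB genes were lower with si1 in 17 of 26, or 19 adjusted over the list alone, and higher in 1 (median -0.43, adjusted p = 3.9e-09). SDF4, ENOPH1 and DHRS2 were 3.56-fold, 3.09-fold and 3.04-fold higher with si1, and TWF1, CHIC1 and GTF3C6 5.59-fold, 4.77-fold and 4.28-fold lower.

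To compare the targets, the siRNAs of each were set against the 4 siRNAs of the other targets. All 34 interferon genes were higher with ZBTB38 siRNAs (median 2.90) and lower with ZBTB4 siRNAs (median -2.40, adjusted p = 1.3e-205), with BST2 104-fold higher and 166-fold lower. Cholesterol genes were higher with ZBTB33 siRNAs in 21 of 25 (median 0.62, adjusted p = 7.6e-21) and lower with ZBTB38 siRNAs in 21 (median -0.62, adjusted p = 3.7e-09). Hypoxia genes were higher with ZBTB38 siRNAs in 25 of 26 (median 0.82, adjusted p = 1.3e-30) and lower with ZBTB33 siRNAs in 21 (median -0.60, adjusted p = 2.0e-19). Each value in this comparison, that of BST2 included, also carries the changes of the other targets. Against Scr, the ZBTB33 medians of both lists were smaller in size. With ZBTB33 si2 alone against Scr they were 0.09 for hypoxia and 0.01 for cholesterol genes. YAP and TEAD target genes were higher with ZBTB4 siRNAs in 20 of 23 (median 0.56, adjusted p = 2.8e-08). With ZBTB33 siRNAs, PADI2 was 6.95-fold higher than with the others, LOX, which crosslinks collagen, 10.5-fold lower and LINC00520 7.92-fold lower. Against Scr, however, PADI2 changed by -0.51 with ZBTB33 si1 and 2.45 with si2. LOX changed by -2.06 with si1 and 0.27 with si2 (adjusted p = 0.51), and LINC00520 by 0.47 and -0.68 (adjusted p = 0.20 and 0.15). LINC00659 (9.16-fold), RFX6 (7.51-fold) and ARC (14-fold lower) reversed with the run term, to -0.47 ± 0.61, -0.76 ± 1.08 and 1.02 ± 2.24, with 1 to 4 counts each in PrEC. These tests called 10426 genes for ZBTB33, 11243 for ZBTB38 and 11166 for ZBTB4. The 3 targets stand in 3 different runs of sample numbers, so target and run cannot be told apart, and the run term left 3228, 4878 and 5751 genes and a minimum of 1.5-fold 2653, 3444 and 3522.

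Genes called alike with all 6 siRNAs numbered 725, of which 484 were higher and 241 lower, against 4.38 and 2.74 for independent lists and 0 in the simulated data sets. SLC36A1 rose 4.25-fold, TC2N 3.76-fold, GDF15, a stress-induced cytokine, 3.39-fold and WSB1 2.62-fold on average, and PTPMT1, NAT8L, ADM2, NRBF2 and THSD7A also stood among the 10 largest rises. APOBEC3G, an antiviral cytidine deaminase, fell 3.66-fold, STEAP4 2.94-fold, S100A9, a calcium-binding protein of inflammation, 2.87-fold and ITGB6 2.51-fold. DMBT1 fell 4.33-fold. With the run as a term, DMBT1, ITGB6 and NAT8L were called with 4, 5 and 2 of the siRNAs, at mean log2 changes of -2.06, -1.22 and 3.14, against -2.11, -1.33 and 1.66 without it. NAT8L has 4 counts in PrEC and DMBT1 16. For THSD7A, with no count in PrEC, the term cannot be estimated. With a minimum of 1.5-fold, 75 genes were left, with the run term 207, and without genes whose 3' UTR holds a siRNA-linked word 301. The mean changes of the targets had r = 0.368 for ZBTB33 and ZBTB38, 0.332 for ZBTB33 and ZBTB4 and 0.230 for ZBTB38 and ZBTB4 across genes. Their covariances were 0.0975, 0.0863 and 0.107, against at most 0.0201 in simulated data sets, in which the shared Scr libraries alone gave r of 0.639 to 0.677.

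Of the remaining lists, apoptosis regulators gave camera adjusted p of 0.722 for ZBTB33, 0.921 for ZBTB38 and 0.848 for ZBTB4. Wnt ligands and beta-catenin targets gave 0.879, 0.921 and 0.643, basal epithelial genes 0.0519, 0.291 and 0.637, and RNA interference genes 0.304, 0.119 and 0.0843. For ZBTB33, the basal list was called without Scr replicate 1 or 2, si1 replicate 3, or si2 replicate 1 or 3 (adjusted p = 0.0235 to 0.0491), and not without any 1 of the other 4, among them si2 replicate 2. That library held the most PrEC transcripts, and all 19 basal genes measured in PrEC and Scr were higher in PrEC. The basal list was also called without a low-count filter (0.00318), with the run term (0.0452) and without genes that hold siRNA-linked words (0.0103). The TGF-beta list (adjusted p = 0.0649) was called without Scr replicate 1 (0.0430) or si2 replicate 1 (0.0483), without a low-count filter (0.00155), with the run term (0.0362), with si1 alone (0.00831) and without genes that hold siRNA-linked words (0.0104). Without a low-count filter, the interferon (0.0309), DNA methylation (0.00607) and NRF2 lists (0.00788) were called as well. The interferon list was called in opposite directions with each siRNA alone, and with si2 alone the DNA methylation (0.0159) and mesenchymal lists (0.00142) were. The list of genes described as regulated by these ZBTB proteins gave 0.196, 0.555 and 0.204. Among its members, CDKN1A rose by 1.66 ± 0.07 for ZBTB38 and 1.97 ± 0.07 for ZBTB4, and FOSL1 by 1.31 ± 0.07 and 0.82 ± 0.06. For ZBTB33, CDKN1A changed by 0.87 with si1 and 0.12 with si2 (adjusted p = 0.274), and FOSL1 by 0.80 and 0.01 (adjusted p = 0.904). Neuroendocrine genes (4 measured) gave 0.879, 0.921 and 0.803, and germline genes (2 measured) 0.960, 0.921 and 0.675.

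The last comparison asked how PrEC differs from PC3 with Scr, and how the 3 genes are expressed in each. PrEC expressed a basal epithelial programme: all 19 measured basal genes were higher (median log2 difference 4.09, camera adjusted p = 7.6e-31, and adjusted p = 0.00567 with an estimated correlation). KRT14 stood at 24800 ± 2000 CPM (SD, n = 3) against 2.33 in Scr, and KRT17 at 17700 against 8.59, both basal keratins. COL17A1, a hemidesmosome collagen, differed by 7.55 ± 0.08 (SE) and DSG3, a desmosomal cadherin, by 12.80 ± 0.15. ZBTB33 was at 49.3% of Scr (log2 difference -1.02), ZBTB38 at 82.8% (-0.27) and ZBTB4 at 137% (0.46). With library totals without scaling factors, the median of all genes moves from -0.02 to -0.66 and ZBTB4 turns to -0.19 (adjusted p = 0.0185), so its direction holds only relative to the other genes.

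Genes of the cell cycle were lower in PrEC: 30 of 30 genes of G2 and mitosis (median -2.27, adjusted p = 7.5e-17, against adjusted p = 0.108 estimated) and 33 of 36 of DNA replication (median -1.90, adjusted p = 2.6e-11, against adjusted p = 0.108 estimated), with 2 of the latter higher. MKI67, a proliferation marker, differed by -3.32 ± 0.06, FOXM1 by -3.79 ± 0.08 (15.9% overlap with ITFG2) and RRM2 by -3.18 ± 0.07 (20.2% overlap with AC007240.1). Interferon genes were lower in 30 of 34 and higher in 2 (median -1.82, adjusted p = 1.2e-09, against adjusted p = 0.130 estimated), with OAS3 at -3.54 ± 0.06. Luminal prostate genes were lower in 10 of 13 and higher in 2 (median -2.17, adjusted p = 0.00135, against adjusted p = 0.108 estimated), with TMPRSS2 at -7.05 ± 0.17 and HOXB13 at -4.15 ± 0.10. DNA methylation and corepressor genes were lower in 21 of 28 and higher in 6 (median -1.09, adjusted p = 0.00174, against adjusted p = 0.151 estimated), with DNMT1, the maintenance methyltransferase, at -3.11 ± 0.06 and UHRF1 at -3.60 ± 0.10. RNA interference genes were lower in 12 of 13 (median -0.72, adjusted p = 0.0108, against adjusted p = 0.130 estimated), with AGO2 at -3.01 ± 0.06. Wnt genes were lower in 14 of 22 and higher in 4 (median -1.63, adjusted p = 0.0351, against adjusted p = 0.220 estimated), with FOSL1 at -3.50 ± 0.07.

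Cholesterol genes were higher in PrEC in 17 of 25 and lower in 5 (median 0.81, adjusted p = 0.00101, against adjusted p = 0.108 estimated), with FDFT1 at 3.78 ± 0.06. Growth arrest genes were higher in 18 of 29 and lower in 7 (median 0.64, adjusted p = 0.0220, against adjusted p = 0.130 estimated), with CDKN1A at 5.60 ± 0.09 and BTG2 at 5.49 ± 0.08. Hypoxia genes were higher in 19 of 26 and lower in 6 (median 0.66, adjusted p = 0.0262, against adjusted p = 0.151 estimated), with ANGPTL4 at 5.91 ± 0.08. TGF-beta targets were higher in 12 of 20 and lower in 6 (median 0.82, adjusted p = 0.0392, against adjusted p = 0.371 estimated). With library totals, the medians of the last 3 lists were -0.01, 0.02 and 0.18, and their calls ended (adjusted p = 0.0516, 0.139 and 0.0973). The call of the TGF-beta list also ended with the run term (adjusted p = 0.122), without a low-count filter (0.0775) and without any 1 of the 6 libraries (adjusted p = 0.0533 to 0.127). The other 15 lists gave adjusted p from 0.0636 to 0.99. Among those, mesenchymal genes were lower in 13 of 22 and higher in 8 (median -1.03), and the list was called without any 1 of the Scr libraries (adjusted p = 0.0360 to 0.0446). Oxidative phosphorylation genes were higher in 18 of 28 and lower in 5 (median 0.36), and that list was called without any 1 of the PrEC libraries (adjusted p = 0.0160 to 0.0332), without a low-count filter (0.0474) and with the run term (0.00932). Nucleolar genes were called without a low-count filter (0.0239), and with all 24 libraries in 1 fit mesenchymal (0.0314), NRF2 (0.0284) and lysosome genes (0.0437) were.

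Among the named genes, S100A8, a calcium-binding protein of inflammation, reached 2300 CPM in PrEC against 0.178 in Scr. Those with no count in Scr were at least 5060-fold higher in PrEC for MT1E, 4650-fold for CRCT1, 3350-fold for TSPAN14, 3200-fold for IGFL2, 3190-fold for THBS2, 3120-fold for PRXL2A, 2450-fold for CERS3, 2250-fold for DEFB1 and 2050-fold for LCE3D. With 2 counts each in Scr, the ratio was 21000 for CAVIN1 (interval 5820 to 174000) and 17900 for KRT6C (4950 to 148000). In the other direction, CLDN3 was at least 523-fold and SERPIND1 at least 277-fold lower in PrEC, where neither had a count. With 1 or 2 counts in PrEC, the ratio was 2280 for SHISA3 (interval 408 to 89900), 2180 for MUC6 (390 to 85900), 1650 for PRAME, a cancer-testis antigen (295 to 65000), and 1610 for TFF2 (288 to 63500). It was 1360 for PLCXD3 (376 to 11200), 1040 for GPR4 (187 to 41200) and 940 for MUC5AC, a mucin (260 to 7770). COL6A3, NR2F1 and NUP210 were 1260-fold, 780-fold and 779-fold lower in PrEC. All 24 lay on 1 side of the Scr mean in the 3 PrEC libraries, which the choice of these genes makes likely.

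Markers of other cell types were low in PrEC. Leukocyte markers reached at most 0.648 CPM (LAPTM5), endothelial markers 0.448 CPM (TEK), smooth muscle markers 6.93 CPM (ACTA2, 30.1% overlap with ACTA2-AS1) and fibroblast markers 8.77 CPM (COL1A1, 38.1 CPM in Scr). In Scr, the endothelial marker PECAM1 stood at 15.9 CPM and KDR at 6.88 CPM. Among epithelial markers, KRT8 stood at 1450 CPM and KRT5 at 19900 CPM in PrEC and at 469 and 1.69 CPM in Scr. PrEC and Scr differed in 13956 of 16512 genes (6910 higher and 7046 lower in PrEC). A fit with library totals called 4379 higher and 9868 lower. The 10 most abundant genes took 13.52% to 14.58% of counts in PrEC and at most 4.50% in PC3 libraries, and mitochondrial genes 10.22% to 11.04% against 2.58% to 3.93%. PrEC also differed in medium, range of passages and transfection, which cannot be told apart from the cell type.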

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

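Of the tests in this part, the comparisons of si1 with si2 and the counts of other splits were planned before their results were seen, and the others were chosen after, among them the test of chance deviation of the Scr libraries, which replaces a planned ratio that the choice of the genes would have fixed.

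The ZBTB33 siRNAs differed in their effect on ZBTB38, which was 0.70 higher on the log2 scale with si1 than with si2 (SE 0.05, adjusted p = 6.6e-11, n = 3 each). They also differed in the interferon list, whose median was -0.69 for si1 minus si2, with 28 of 34 genes lower and 1 higher (camera adjusted p = 4.5e-13, and adjusted p = 1.4e-05 with an estimated correlation). All 3 si1 libraries had medians below Scr and all 3 si2 libraries above. The difference between the siRNAs was tested itself in both cases.

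The first pattern is that ZBTB33 si1 and si2 changed different genes, although both left about 10% of ZBTB33. As the whole cause, matches of the 2 leading words of each siRNA to 3' UTRs, acting through the matched genes alone, are argued against. Of genes without these words, 61.0% differed between si1 and si2, against 68.5% of genes with them. Other shifted words, such as TACATCT (z -12.0), were not counted, so a larger share through other matches stays open. Matches of the kind microRNAs make may be part of it, since the 7-base words most shifted were ATACATC (z -21.0, genes lower with si1) and GCACTAT (z 15.5, genes lower with si2), and ZBTB33's own transcripts hold both. Genes with the leading words were lower than Scr in 54.9% of cases with si1 (25.5% of genes without) and 34.9% with si2 (16.8%). The words were chosen from the same libraries, so these shares in part restate that choice. Of the siRNAs, 6 of 6 had their leading word in their own target (chance 0.00098), while ZBTB38's 3' UTR of 3816 bases holds 1 copy of GCACTAT. It also holds 1 copy of TCACTTA, the leading word of ZBTB4 si1. Secondary effects of matched genes and roles of ZBTB33 itself stay open, as untested, because the siRNA sequences are not given.

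The second pattern is that si1 and si2 changed genes more alike for ZBTB38 and ZBTB4 than for ZBTB33. The shared Scr libraries are argued against, since the ZBTB33 pair shares the same Scr libraries and its covariance was at most 12.4% of that of the other pairs. A library or sequencing batch common to the PC3 and PrEC libraries of a run cannot be told apart from the target: the covariance with the PrEC difference between runs was 3.8% of the variance of the ZBTB4 changes and 1.8% for ZBTB38, but each run holds 1 PrEC library. Nor can a culture or transfection batch of the PC3 cells be told apart, since 58.7% of the PC3 variance lay between runs and no Scr library used here lies in the runs of ZBTB38 and ZBTB4. The PC3 batch covers the opposite interferon changes of these targets as well, and a role of the proteins stays open beside it.

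The third pattern is that 725 genes moved alike with all 6 siRNAs. Chance deviation of the 3 Scr libraries is argued against, since genes called without 1 Scr library changed against that library by 92.0% to 101.8% of the change against the other 2 in the median, and 99.8% of them in the same direction. Matches of the 2 leading words of the Scr siRNA to 3' UTRs as the whole cause are argued against as well, since 90.6% of the genes higher with all 6 lack them. Other shifted words, such as GACAGTA (z 8.3), were not counted, so a larger share through other matches stays open. Matches may account for part, since the word AGACGTA stood at z 8.6 in the mean of the siRNAs minus Scr. Of genes with the words, 15.3% were higher with all 6 against 3.65% without, but the words were chosen by this same shift, so these shares add no separate support. A difference in how the Scr cells were handled and a function common to the proteins stay open, as untested.

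Other splits of the libraries were counted for each result. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the compared groups alone, the real split gave 8747 and 7759 genes for ZBTB33 si1 and si2 against Scr, 10061 and 9480 for ZBTB38 and 10247 and 7350 for ZBTB4. It gave 9332, 1583 and 2504 between the siRNAs of ZBTB33, ZBTB38 and ZBTB4, and 13956 for PrEC against Scr. In each case the highest other split gave 0 genes (1 of 10 as large). For the PrEC lists, the real split gave 12 and the others 6 to 9 (1 of 10). Those other splits called 0 genes, so camera at the preset correlation calls lists without any gene called.

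The next splits shuffle single libraries. Chance here means how libraries fell into groups, and differences between whole siRNAs or runs were not tested. In fits of a target's siRNAs and Scr alone, chance can be excluded for genes called alike for ZBTB38 (7798, highest other 1553, 1 of 60 splits) and ZBTB4 (5978, highest other 1700, 1 of 60). It cannot for ZBTB33, where 3 of 60 splits gave as many (2951, highest other 5050). The other splits that did so took 1 whole siRNA group as the control, so they follow the difference between si1 and si2. For lists, chance can be excluded for ZBTB33 (11, highest other 8, 1 of 60) and ZBTB4 (17, highest other 18, 2 of 60), but not for ZBTB38 (12, highest other 18, 7 of 60). Chance between single libraries can be excluded for each target against the others, fitted as 2 groups of the 18 siRNA libraries (4711, 6537 and 6263 genes, highest other 7, 1 of 60 each). It can also be excluded for genes alike with all 6 siRNAs (725, highest other 28, 1 of 40). Both kinds of split break up the libraries of each siRNA, so they do not exclude chance between siRNAs or runs. The splits decide nothing for the correlations between targets, where 35, 38 and 39 of 40 gave values as high (real 0.368, 0.332 and 0.230, highest others 0.915, 0.928 and 0.946), because with shared Scr libraries data without any change already give r of 0.639 to 0.677. The covariances (0.0975, 0.0863 and 0.107) lie above the highest of 0.0201 in those data.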

How the results depend on the processing

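Leaving out genes with siRNA-linked words was chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the labels carry no replicate numbers that join libraries across groups. The fall of each target with its own siRNAs, and its difference between PrEC and Scr, kept direction and call under DESeq2 size factors, the DESeq2 test, no low-count filter and leaving out any 1 library. Under library totals, ZBTB4 in PrEC turned to -0.19, genes between ZBTB38 si1 and si2 split into 879 higher and 1406 lower, PrEC genes into 4379 and 9868 and PrEC lists into 2 and 7. The cause was not tested unless stated. A minimum of 1.5-fold, which removes small changes by construction, left 2958 and 1250 genes for ZBTB33 si1 and si2, 3695 and 4050 for ZBTB38, 3676 and 3587 for ZBTB4, 290, 2816 and 2386 alike for ZBTB33, ZBTB38 and ZBTB4, 3459, 281 and 895 between siRNAs, 2653, 3444 and 3522 against the other targets and 75 alike with all 6. One test of the mean called 6388 genes for ZBTB33. Fits of the compared groups only, which use fewer libraries, called 1583 genes between the ZBTB38 siRNAs and 2504 between the ZBTB4 siRNAs. The run term called 3552 and 3687 genes for ZBTB38, 3970 and 3830 for ZBTB4, 2820 and 2725 alike, 3228, 4878 and 5751 against other targets and 207 with all 6. It turned RFX6 to 0.40 (ZBTB38) and -0.76 (ZBTB33 against others), MSMP to 1.66, LINC00659 to -0.47, ARC to 1.02 (ZBTB33 against others), TEX14 to 0.17 (ZBTB38), DDX4 to 1.85 and NPM1 to 0.12 (ZBTB4), and ended 45 other calls of 545 (each a named gene in 1 comparison). PrEC, which carries the term, has 1 to 37 counts of the reversed genes but 33079 of NPM1. With 1 PrEC library per run, the term also widens standard errors, so lower counts of calls do not measure a run effect. Without genes holding siRNA-linked words, 3228 were alike for ZBTB4 and 301 with all 6, with fewer genes tested. Lists called for ZBTB33, ZBTB38, ZBTB4 and PrEC numbered 6, 8, 11 and 1 with an estimated correlation and 22, 23, 27 and 25 with fry, which does not compare a list with other genes. For ZBTB33, the median of G2 and mitosis was -0.04 with si1 alone, and those of interferon and hypoxia were 0.28 and 0.09 with si2 alone. Leaving out 1 library moved the count between the ZBTB38 siRNAs to between 1527 (without si1 replicate 1) and 2345, and genes alike with all 6 to between 557 and 856. Depth limits genes near 0.132 to 0.177 CPM, the level of 3 counts in a library.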

Other observations

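Beyond the comparisons of the report, some genes of PrEC had almost no counts in any PC3 library. Of 10275 genes at 5 CPM or more in PrEC, 107 had at most 10 counts over the 21 PC3 libraries. They lay next to each other on the chromosome, among the 10275 genes, in 13 pairs, against a mean of 1.12 and at most 5 in 1000 shuffles. The shuffles do not keep gene families together, and the 107 include neighbours of 1 family, such as HOXD9, HOXD10 and HOXD11. On chromosome 17 (GRCh38, 42101404 to 42388568), DHX58, KAT2A, RAB5C, GHDC, STAT5B, STAT5A and STAT3 had 0 to 15 counts each over the PC3 libraries. In PrEC, STAT3, a transcription factor of cytokine signalling, stood at 122 CPM, RAB5C at 100 CPM (30.4% overlap with ENSG00000267261) and KAT2A, a histone acetyltransferase, at 41.9 CPM (10.7% overlap with the same). On chromosome 10, PRXL2A and TSPAN14 (140 and 150 CPM in PrEC) had 12 and 21 PC3 counts. On chromosome 15, PARP6 and HEXA (40.0 and 60.1 CPM in PrEC) had 0 and 12, and HEXA exons overlap ENSG00000261460 by 17.9%. These regions were chosen after the values were seen. RAB5C, STAT3, PRXL2A, TSPAN14 and HEXA had more than 10 PC3 counts, and STAT5A stood at 2.96 CPM in PrEC. Those genes are therefore not among the 107, and the count of pairs does not cover them.

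Transcripts of 48 genes with at least 50 CPM in PrEC and at most 3 counts over the Scr libraries reached 0.246% of their PrEC level in ZBTB33 si2 replicate 2 and 0.230% in ZBTB38 si2 replicate 2. In the other PC3 libraries they reached at most 0.052%. The genes were chosen after the values were seen, and Scr is low in them by selection. Of the genes named for ZBTB33, ZBTB38 or all 6 siRNAs, 6 in the first library and 4 in the second would draw 10% or more of their level from this share. Of those called with all 3 libraries of that siRNA, KRT17 with ZBTB33 si2 lost its call without the library (log2 change 1.22 to 0.31), and the others did not.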
